A study of Mus musculus with 9 samples.

How the data were processed

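Circular RNAs (circRNAs) were measured in the livers of male C57BL/6J mice, an inbred laboratory strain, at 20 weeks of age. Per the labels, 3 groups of mice were compared. Control mice ate chow for 17 weeks, and no gavage is listed for them. High fat diet mice ate a diet with 45% of its energy from fat for 17 weeks and received saline by gavage for the last 5 weeks. Metformin mice ate the same diet and received 3 mg of metformin per kg body weight per day by gavage for the last 5 weeks. Metformin is a biguanide drug used to lower blood glucose in type 2 diabetes. Each group had 3 arrays, and each array held liver RNA pooled from 4 mice, so that the spread between arrays is the spread between pools and is smaller than that between single mice. Per the labels' protocols, RNA was extracted from 15 mg of liver, and 5 µg of it was digested with RNase R for 30 minutes, an exonuclease that degrades linear RNA and spares circles, before Cy3 labelling.

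The samples were hybridised to a 1-colour mouse circRNA array in Agilent format. Per the file headers, spot intensities were extracted with Agilent Feature Extraction 11.5.1.1 from a grid built on mouse genome build mm9; the submitters' processing notes name version 10.7. The deposited processed intensity of each spot is background-subtracted and detrended per the file headers, and is not scaled between arrays. The deposited median intensities of each spot and of its local background are raw. The authors also deposited a table of log2 values per circRNA. Set against the scanner values, those log2 values followed the rank of the circRNA probe's intensity minus that of a partner probe on every array (Spearman correlation 1.00 above the floor), had the same median of 6.51 on each array, and stood at a floor of -3.32 wherever the partner was as bright or brighter. The floor also held 62 to 127 circRNAs per array whose probe was brighter than its partner, by less than 0.1 intensity units. Their scale is therefore log2 of a quantile-normalised difference; the direction is that of the signal, and how the floor was set is not given in the sources used here.

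Each array had 62617 spots, of which 1439 were controls. The remaining spots carried 61079 probes. These were 30534 circRNA probes, 30534 partner probes that bear the same name with the ending _neg, and 11 probes for foreign transcripts. What the partner probes were designed to bind is not given in the sources used here; they were treated as a paired reading of signal that need not come from the circle. Each circRNA had 1 probe. Of the circRNA probes, 14043 were named by position, and the others by a number or code. Positions are given as the probe names give them. They are mm9 coordinates: the largest on chromosome 1 was 196912474, beyond the last gene end of 195291439 in the GRCm38 gene table at hand. The files used here do not pair probes with host genes, and the builds differ, so no circRNA was given a host gene, and positions were not set against gene models, exons or introns. For the same reason the 24 host gene lists fixed before the data were examined, among them markers of hepatocytes and of other liver cells, and the circRNAs of 6 host genes chosen in advance, were not tested. Chromosomes and kinds of probe name were tested as sets in their place.

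The processed intensity was brought to log2, and the 75th percentile of each array over all probes other than controls was subtracted. Spots flagged as outliers by the scanner software were left out, and spots of the same probe were averaged. No circRNA probe was saturated. A circRNA was tested if its probe was well above background on all 3 arrays of at least 1 group, which kept 25864 circRNAs (84.7%). The 3 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend), so that they shared an estimate of the spread (6 residual and 5.72 prior degrees of freedom), and the 3 differences between groups were tested. A circRNA was called at an adjusted p (Benjamini-Hochberg within the comparison) under 0.05. Where a probe was not well above background on any array of a group, the fold is given as a lower bound. The bound is taken against the mean, over that group's arrays, of the higher of the dim probe's own value and the lowest value of any probe well above background.

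Circles with overlapping spans were joined into loci, and 1066 loci with 3 or more tested circRNAs (4987 circRNAs) were tested in the same way on the mean of their probes. This unit was chosen after the data were seen. Sets were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The covariance of the diet difference (high fat diet minus control) and the metformin difference (metformin minus high fat diet) was set against 100 simulated data sets of unchanged groups, since both differences hold the same high fat diet arrays. Simulated circRNAs varied independently and with the same spread on every array, unlike in these data. The SD over simulations therefore understates the uncertainty. Detection and control probes were compared by exact permutation tests, two-sided, for which 3 arrays against 3 cannot give a p below 0.1.

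The fits were tested on simulated data with the levels and missing values of these arrays and 200 changed circRNAs among 25864. The spread of each circRNA was drawn from the distribution fitted over all circRNAs, without regard to its own level or spread. Simulated circRNAs varied independently and with equal spread on all arrays, unlike in these data. The shares recovered therefore describe the simulated arrays and may differ from those of the real ones. For high fat diet against control, 74% of circRNAs changed 2-fold and 96% of those changed 3-fold were recovered, but 8.0% of those changed 1.5-fold. For metformin against high fat diet the shares were 68%, 92% and 20%, and for metformin against control 76%, 98% and 16%. The number of arrays limits the precision. The median standard error of a log2 difference was 0.165 for high fat diet against control, 0.166 for metformin against high fat diet and 0.166 for metformin against control.

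The circRNAs named were chosen by a rule fixed before the data were examined. It takes the called circRNAs with the largest change, and where fewer than 10 are called in a direction, it fills the list to 5 (3 for metformin against control) with the smallest unadjusted p among circRNAs whose groups do not overlap. It also takes 5 circRNAs per direction with an unadjusted p under 0.05 and opposite signs in the diet and the metformin comparison. Because numbers and codes could not be paired with genes, at most 2 of them are printed per comparison and direction. The rest are summarised.

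Alternatives chosen before the data were examined were 2 other scalings, normexp background correction (offset 50), the authors' deposited values, 2 other filters on dim probes, slide, array column and replicate number as blocks, a variance model with trend and robust fitting, fits of only the groups compared, other thresholds, another detection call, and leaving out each array. Normexp was run on median intensities, since the mean intensities it was planned for were not among the columns used. A mean over several probes of a circRNA was not needed. Those chosen after the data were seen were the log2 ratio to the partner probe, the partners tested alone or together with the circRNA probes, array weights, leaving out both arrays that stood apart, tests within a column of the slide, other locus sizes, and covariances with the shared arrays split between the differences.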

Results

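Liver circRNAs were profiled on 9 arrays, 3 each from chow-fed control mice, mice on a high fat diet, and mice on the same diet given metformin. Each array carried pooled RNA from 4 mice. The share of all probes well above background was 81.5% ± 2.36 (SD, n = 3) in controls, 77.0% ± 5.35 (SD, n = 3) on the high fat diet and 78.8% ± 8.19 (SD, n = 3) with metformin. Exact permutation tests of these shares gave p = 0.3 for high fat diet against control, p = 0.8 for metformin against high fat diet and p = 0.8 for metformin against control, but 0.1 is the smallest p possible, so that they could not pass a threshold of 0.05 and whether the shares differ was left open. The difference between high fat diet and control was -4.48 percentage points, -1.81 without high fat diet replicate 2 (exact permutation test, p = 0.6) and -7.16 without high fat diet replicate 1 (p = 0.1). High fat diet replicate 2 (71.7%) and metformin replicate 3 (69.4%) had the lowest shares, and the other 7 arrays lay between 77.0% and 84.2%. Between arrays, levels of circRNAs correlated at 0.973 to 0.993, a correlation across circRNAs, which are not independent replicates.

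**Figure D1:**
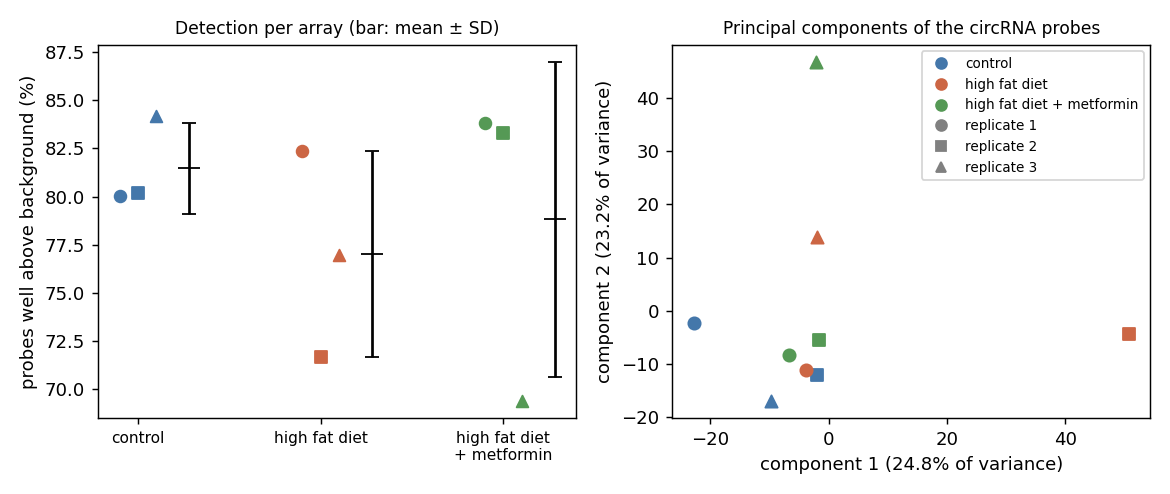
The left panel plots the percentage of probes well above background on each array, by group, with mean and SD, on an axis that does not start at 0; the right panel plots the first and second principal components of the circRNA probes. High fat diet replicate 2 lies apart on component 1 (24.8% of variance) and metformin replicate 3 on component 2 (23.2%), and these arrays have the lowest detection, 71.7% and 69.4%.

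The first comparison asked which liver circRNAs differed after 17 weeks of high fat diet. The high fat diet mice also received saline by gavage, which is not listed for the controls. In comparisons with control, diet and gavage therefore cannot be told apart. A locus on chromosome 19 (mm9 43579012 to 43590352) with 3 circRNAs was lower on the high fat diet, by a mean log2 difference of -1.02 ± 0.149 (SE, n = 3 arrays per group, limma, adjusted p = 0.0209). It was the 1 locus called among 1066. All 3 of its circRNAs were lower in every high fat diet array than in every control array. The brightest of them, spanning 43579012 to 43582483, had a level of 3.85 ± 0.00491 (SD, n = 3; log2 above the array's 75th percentile) in controls and 3.01 ± 0.142 on the diet. The circRNA from 43579012 to 43579416 stood at 1.13 ± 0.0310 in controls and -0.08 ± 0.222 on the diet, and the one from 43581812 to 43590352 at 1.15 ± 0.0479 and 0.16 ± 0.220. For the circRNA from 43579012 to 43579416 the _neg partner was the brighter probe on every array, with a mean of 1.38 against 0.43. Its signal therefore did not exceed the paired reading. Taken singly, these 3 circRNAs missed the threshold in the main fit, with log2 differences of -0.84 ± 0.132 (adjusted p = 0.169), -1.21 ± 0.258 (adjusted p = 0.281) and -0.997 ± 0.165 (adjusted p = 0.169). The brightest was called with trend and robust fitting (limma, adjusted p = 0.0160) and with normexp and 75th percentile scaling (adjusted p = 0.0341). With the authors' deposited values it was called too (adjusted p = 0.0462). The _neg partner probes of the 3 circRNAs were lower too, by a mean log2 difference of -0.87, and the log2 ratio of circRNA to partner probe differed by -0.14 (adjusted p = 0.981). The minimum of 3 circRNAs per locus was chosen after the data were seen, and with a minimum of 2 no locus was called. The locus also missed the threshold without any filter on dim probes (adjusted p = 0.124), with the array column on the slide as a covariate (-1.09, adjusted p = 0.0966), with the authors' deposited values (adjusted p = 0.327), and without control replicate 1 (adjusted p = 0.134), control replicate 2 (adjusted p = 0.134), high fat diet replicate 2 (adjusted p = 0.0774) or high fat diet replicate 3 (adjusted p = 0.140). Within column 1 of the first slide, which held the 3 control arrays and 1 high fat diet array, its difference was -0.86, a value that rests on that array.

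**Figure D2:**
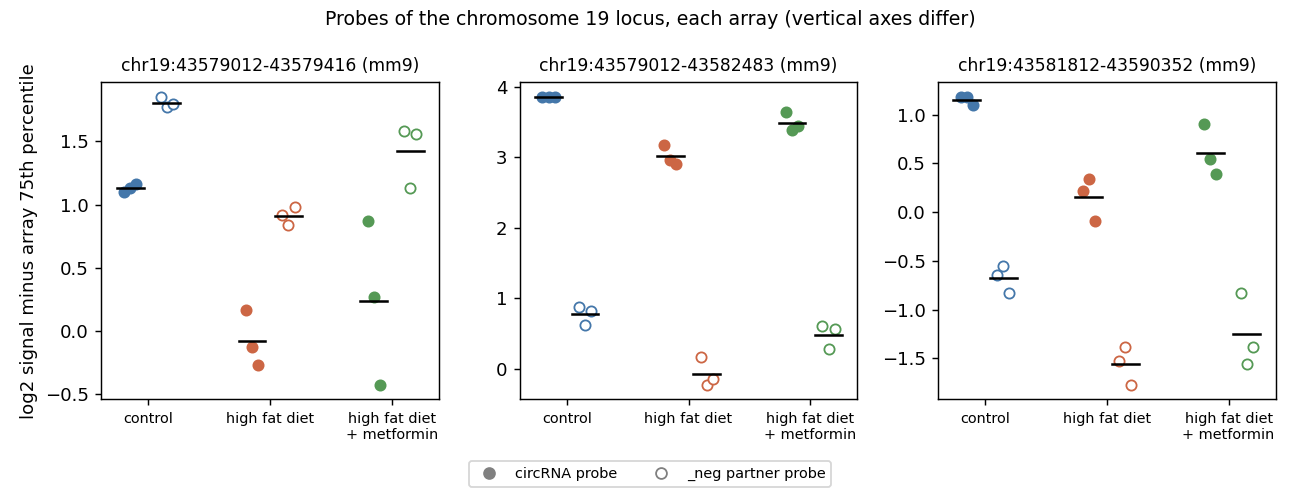
Each panel plots 1 circRNA of the chromosome 19 locus, as log2 signal minus the array's 75th percentile, for each array by group, with filled points for the circRNA probe, open points for its _neg partner and lines for group means; vertical axes differ between panels. In all 3 panels the high fat diet arrays lie below the control arrays for both probes, with mean log2 differences of -1.02 for the circRNA probes and -0.87 for the partners.

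No single circRNA passed the threshold in this comparison (limma, 0 of 25777 tested; smallest adjusted p = 0.0899). At an unadjusted p under 0.05 there were 1868 circRNAs (7.25%), where 5% would be 1289; 533 of these were higher on the high fat diet and 1335 lower. Another split of the same 6 arrays gave 2024, and there were 1381 with the array column as a covariate and 1298 for the log2 ratio to the partner probe. Without control replicate 1 the count was 1280, and without high fat diet replicate 1 it was 2752. The circRNA with the smallest p was mmu_circ_0015831, at -2.66 ± 0.247 (SD, n = 3) in controls and -1.48 ± 0.0692 on the diet, a log2 difference of 1.18 ± 0.144 (SE, adjusted p = 0.0899). It was called with normexp and quantile normalization (adjusted p = 0.0116) and with normexp and 75th percentile scaling (adjusted p = 0.00708). Trend and robust fitting (adjusted p = 0.0160) and only probes well above background on all 9 arrays (adjusted p = 0.0202) called it too. In the other alternatives that tested it the adjusted p was above 0.05. Other circRNAs with higher values on the diet that missed the threshold in the main fit lay on chromosome 12 (104384512 to 104387291; 1.22 ± 0.211, adjusted p = 0.186) and chromosome 3 (88418429 to 88420576; 1.09 ± 0.192, adjusted p = 0.187). Both were called with normexp and 75th percentile scaling (limma, adjusted p = 0.0376 and 0.0466). For mmu_circ_0003685 the difference was 1.14 ± 0.202 (adjusted p = 0.187). A circRNA on chromosome 13 (58939157 to 58962916) was not well above background on any control array and was on all 3 high fat diet arrays, at least 3.37-fold higher (adjusted p = 0.169). Its _neg partner had the higher mean over all arrays (-2.81 against -4.58) and differed by 0.93 ± 0.373. With the array column as a covariate the chromosome 13 circRNA was called (adjusted p = 0.00109), where its log2 difference of 4.67 rests on control values near background. Among the 5 circRNAs with lower values, mmu_circ_0001100 had a log2 difference of -1.51 ± 0.238 (adjusted p = 0.169) and mmu_circ_0007806, among the brighter ones with a control level of 3.15 ± 0.244 (SD, n = 3), one of -1.20 ± 0.161 (adjusted p = 0.169). Both were called with normexp and quantile normalization (adjusted p = 0.0279 and 0.0116), normexp and 75th percentile scaling (0.0193 and 0.00708) and trend and robust fitting (0.0160 and 0.00879). With the replicate number as a block mmu_circ_0001100 was called as well (adjusted p = 0.0368). In the other alternatives that tested them the adjusted p was above 0.05. The _neg partners of all 10 named circRNAs differed in the same direction. With normexp background correction and 75th percentile scaling 19 circRNAs were called, 3 higher and 16 lower.

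**Figure D3:**
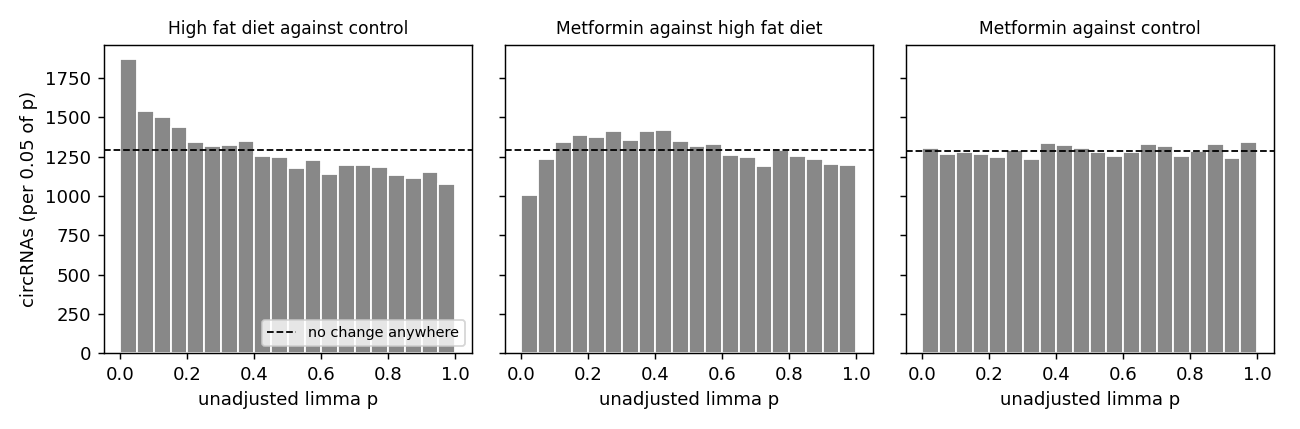
Histograms of the unadjusted limma p of all circRNAs tested, in bins of 0.05, 1 panel per comparison; the dashed line marks the height without any change. The lowest bin holds 1868 circRNAs for high fat diet against control, 1007 for metformin against high fat diet and 1307 for metformin against control, against about 1290 at the dashed line.

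Metformin was compared with high fat diet alone to ask what 5 weeks of the drug did on the same diet. No circRNA (limma, 0 of 25828; smallest adjusted p = 0.207) and no locus (0 of 1066; smallest adjusted p = 0.977) was called. At an unadjusted p under 0.05 there were 1007 circRNAs (3.90%), 599 of them higher with metformin and 408 lower. This was below the 1291 that 5% would be, but the count was 1762 without high fat diet replicate 1 and 1482 without high fat diet replicate 3. The circRNAs with higher values included one on chromosome 15 (102009392 to 102019110), at 1.22 ± 0.234 (SD, n = 3) on the diet and 2.17 ± 0.150 with metformin, a log2 difference of 0.95 ± 0.173 (SE, adjusted p = 0.485). For mmu_circ_0012020 the difference was 1.18 ± 0.209 (adjusted p = 0.442). A circRNA on chromosome 16 (40753629 to 40753947) was at least 1.77-fold higher with metformin (adjusted p = 0.340), against high fat diet arrays on none of which it was well above background, while its _neg partner differed by -0.15 ± 0.447. It was called with the array column as a covariate (adjusted p = 0.0115) and without high fat diet replicate 1 (adjusted p = 0.0219). In the other alternatives that tested it the adjusted p was above 0.05. Also not well above background on any high fat diet array, mmu_circ_0009727 was at least 1.08-fold higher (adjusted p = 0.442). Lower values with metformin were found for the chromosome 12 circRNA named above, with a log2 difference of -1.34 ± 0.211 (adjusted p = 0.340). For mmu_circ_0015831 it was -0.86 ± 0.144 and for mmu_circ_0010188 it was -0.80 ± 0.141 (adjusted p = 0.442 for both); the partner of the latter stood at 0.49 ± 0.214. With the authors' deposited values mmu_circ_0010188 was called (-1.79, limma, adjusted p = 0.0194). A circRNA on chromosome 2 (70922482 to 70927990) differed by -0.76 ± 0.148 (adjusted p = 0.650). In the main fit all of these missed the threshold. The partners differed in the same direction for 4 of the 5 named circRNAs with higher values and 4 of the 5 with lower values. These counts take direction only: the partner stood at 0.19 ± 0.484 for mmu_circ_0009727 and at -0.05 ± 0.237 for the chromosome 2 circRNA. Within column 2 of the first slide, with 2 arrays of each group, 0 circRNAs were called. At the chromosome 19 locus the 3 circRNAs had log2 differences of 0.48 ± 0.132, 0.31 ± 0.258 and 0.45 ± 0.165 (adjusted p = 0.969 for each).

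Whether metformin moved circRNAs back towards the control level was asked of the same data. The chromosome 12 circRNA stood at -2.95 ± 0.344 (SD, n = 3) in controls, -1.73 ± 0.239 on the high fat diet and -3.07 ± 0.315 with metformin. The chromosome 15 circRNA stood at 2.11 ± 0.263, 1.22 ± 0.234 and 2.17 ± 0.150. Both were chosen for opposite signs in the diet and the metformin comparison. The _neg partner turned as well, by 1.08 and then -0.95 on chromosome 12 and by -0.89 and then 0.91 on chromosome 15. Over all arrays the mean of the circRNA probe did not exceed that of its partner (-2.58 against -2.49, and 1.83 against 1.87). A circRNA on chromosome 17 (20492595 to 20497411) had the smallest p for metformin against high fat diet (adjusted p = 0.207), but it had an unflagged value on only 1 control and 1 high fat diet array. Its log2 differences of -2.04 on the diet and 2.22 with metformin both rest on that 1 high fat diet value, without a spread of its group, and no return to the control level is read from them. In the authors' deposited values the metformin difference was -0.10. In all, 331 circRNAs had an unadjusted p under 0.05 in both comparisons, and 328 of these had opposite signs, 85 higher then lower and 243 lower then higher. Unchanged groups that share the high fat diet arrays gave means of 149.3 and 152.3 in simulation, and independent lists would give 8.44 and 31.0. The covariance of the diet and metformin differences was -0.0255 (correlation -0.529 across circRNAs), against -0.0218 ± 0.000596 (SD, 100 simulations; correlation -0.503) for unchanged groups. The difference of the covariances, -0.00368, was 0.00362 without high fat diet replicate 2 and -0.0148 without high fat diet replicate 1, so that its sign rested on replicate 2. With the high fat diet arrays split between the differences, 1 array against 2, so that they shared none, the covariance was -0.00206 to 0.00564 over the 6 arrangements, negative in 2 of them. The diet difference and the difference between metformin and control share the control arrays. Their covariance was 0.0293 against 0.0216 ± 0.000696 (SD, 100 simulations), a difference of 0.00764. In the simulations circRNAs varied independently and with equal spread on all arrays, unlike in these data. The simulated SDs are therefore too small, and neither difference from the simulated covariance is read as an effect. With the control arrays split between the diet difference and that between metformin and control, the covariance was 0.00960 to 0.0183 over 6 arrangements. All 3 control arrays lay in column 1 of the first slide, while 2 of 3 high fat diet and 2 of 3 metformin arrays lay in column 2.

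Metformin was also compared with control, which asks what differed after the diet, the gavage and the drug together. No circRNA (limma, 0 of 25763; smallest adjusted p = 0.290) and no locus (0 of 1066; smallest adjusted p = 0.555) was called, and 1307 circRNAs (5.07%) had an unadjusted p under 0.05, 423 higher and 884 lower with metformin. One of the brightest circRNAs on the array, mmu_circ_0015494, stood at 8.72 ± 0.0256 (SD, n = 3) in controls, 7.74 ± 0.327 on the high fat diet and 7.497 ± 0.240 with metformin, a log2 difference of -1.22 ± 0.179 (SE, adjusted p = 0.290). The difference was called with normexp and 75th percentile scaling (-1.22, adjusted p = 0.0190), with trend and robust fitting (-1.22, adjusted p = 0.00765) and with array weights (-1.31, adjusted p = 0.0247). Its adjusted p was above 0.05 in the other alternatives that tested it, among them normexp with quantile normalization and the log2 ratio to the partner. The _neg partner of mmu_circ_0015494 differed by -0.93 ± 0.268. For mmu_circ_0001100 the log2 difference was -1.50 ± 0.238 (adjusted p = 0.290), while its levels on the high fat diet (-1.67 ± 0.294) and with metformin (-1.65 ± 0.362) differed by less than their spread. It was called with normexp and quantile normalization (adjusted p = 0.0381), normexp and 75th percentile scaling (adjusted p = 0.0281) and trend and robust fitting (adjusted p = 0.0274). In the other alternatives that tested it the adjusted p was above 0.05. Its partner differed by -1.40 ± 0.324, and the partners of all 3 named circRNAs with lower values went the same way. Higher values with metformin were found for circRNAs on chromosome 7 (55979750 to 55982192; 0.95 ± 0.170, adjusted p = 0.351) and chromosome 2 (28396231 to 28406083; 0.81 ± 0.134, adjusted p = 0.290), and for mmu_circ_0004012 (0.80 ± 0.141, adjusted p = 0.351). The partner differed in the same direction for 1 of these 3, and stood at -0.21 ± 0.254 for the chromosome 2 circRNA and -0.05 ± 0.246 for mmu_circ_0004012. With the authors' deposited values the chromosome 2 circRNA was called (8.40, limma, adjusted p = 0.000649), where all arrays of a group stood at the floor. Over all comparisons the partner differed in the same direction for 22 of 26 named differences. This counts direction only, also where the partner's difference was smaller than its SE. At the chromosome 19 locus the mean log2 difference was -0.60 ± 0.149 (adjusted p = 0.861).

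Across circRNAs, the difference measured by a circRNA probe went with that of its _neg partner. For the 21202 pairs with both probes tested, the log2 differences between high fat diet and control correlated at 0.585 (Spearman 0.558); the correlation was 0.485 for metformin against high fat diet and 0.502 for metformin against control. These are correlations across circRNAs, not across independent replicates. Among 1578 circRNAs with an unadjusted p under 0.05 for the diet, the partner differed in the same direction for 91.8%. The deviations of both probes from their group means, which hold no group difference, correlated at 0.402 to 0.592 within single arrays. The partner was the brighter probe of the pair for 21.9% of circRNAs, and tested alone as single probes the partners gave 0 calls in each comparison (limma; 1559, 1005 and 1359 with an unadjusted p under 0.05). Tested as loci, the partners alone gave 1 call for high fat diet against control, the chromosome 19 locus (-0.87, limma, adjusted p = 0.0314). The call of that locus is therefore not particular to the circRNA probes.

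**Figure D4:**
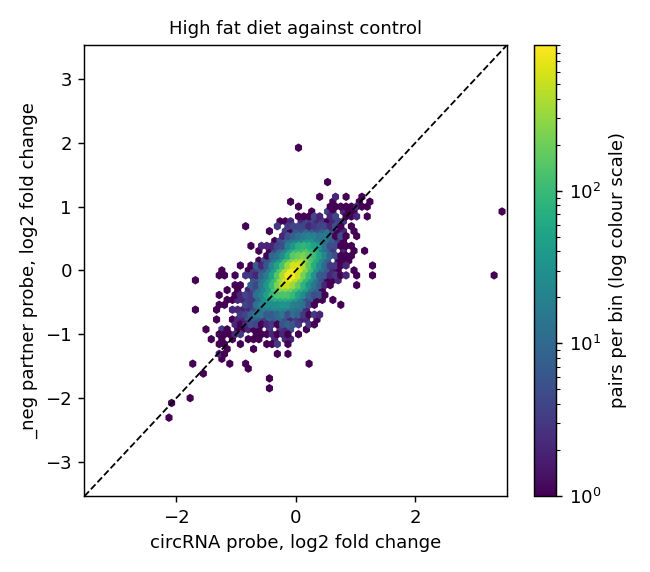
Each bin counts circRNAs by the log2 difference between high fat diet and control of the circRNA probe (horizontal) and of its _neg partner (vertical), on a log colour scale; the dashed line marks equal differences. The 21202 pairs spread along the line, with a correlation of 0.585.

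Linear transcripts were read by control probes for Gapdh and Pgk1, genes of glycolytic enzymes, with 10 spots per probe. The brighter Gapdh probe had a level of 5.78 ± 0.150 (SD, n = 3) in controls, 5.68 ± 0.103 on the high fat diet and 5.79 ± 0.0757 with metformin, above 99.7% of circRNA probes. The brighter Pgk1 probe stood at 2.87 ± 0.209, 2.80 ± 0.143 and 2.98 ± 0.0879. The dimmer Gapdh probe was lower on every metformin array (3.21 ± 0.0470) than on every control array (3.41 ± 0.122), a log2 difference of -0.20 (exact permutation test, p = 0.1, the smallest possible; adjusted p = 0.6 over 12 tests of the 4 probes). None of these tests could pass a threshold of 0.05. None of the 25 sets of circRNAs, 21 chromosomes and 4 kinds of probe name, was called in any comparison by camera at the preset correlation, with an estimated correlation, or by fry. The smallest adjusted p by camera was 0.867 for high fat diet against control, 0.477 for metformin against high fat diet and 0.998 for metformin against control. At an unadjusted p under 0.05, camera gave 0, 1 and 0 sets.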

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

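The alternatives that tested the log2 ratio to the partner probe, the partners, array weights, both arrays that stood apart left out, a column of the slide and other locus sizes, and the test of loci itself, were chosen after the data were seen. No circRNA was called in any comparison with the 2 other scalings, without the filter on dim probes, with the slide as a block, with fits of only the groups compared, with the log2 ratio to the partner, or with the partners alone or added. Causes of changed counts were not tested unless stated.

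For high fat diet against control, 7 circRNAs were called with normexp and quantile normalization, 19 with normexp and 75th percentile scaling, 15 with the authors' deposited values, 1 with probes well above background on all 9 arrays, 1 with the array column as a covariate, 7 with trend and robust fitting, 1 at an adjusted p under 0.1, and 532 at an unadjusted p under 0.05 with a fold of at least 1.5 (126 higher, 406 lower). There were 3 without both arrays that stood apart and 2 within a column of the first slide, whose 1 high fat diet array is assumed to vary like the others. For metformin against high fat diet the counts were 14 with the authors' deposited values, 1 with the array column, 220 at the unadjusted threshold (133 higher, 87 lower), and 0 to 1 when leaving out an array, the 1 without high fat diet replicate 1. For metformin against control they were 3 with normexp and quantile normalization, 6 with normexp and 75th percentile scaling, 23 with the authors' deposited values, 2 with the array column, 3 with trend and robust fitting, 1 with array weights, and 385 at the unadjusted threshold (67 higher, 318 lower).

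Of the circRNAs called with the authors' deposited values, 14 of 15, 13 of 14 and 23 of 23 had all 3 arrays of a group at the floor, with median log2 differences of 10.1, 8.25 and 8.45; without the subtraction the same circRNAs had medians of 0.197, 0.201 and 0.173.

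The called locus count for high fat diet against control, 1, was 0 without the filter on dim probes, 0 with the array column, 0 with the log2 ratio to the partner, 0 with at least 2 and 0 with at least 4 circRNAs per locus, 3 within a column of the slide, 9 at the unadjusted threshold, and 0 to 3 when leaving out an array. It was 0 without control replicate 1, control replicate 2, high fat diet replicate 2 or high fat diet replicate 3, 3 without control replicate 3 and 2 without metformin replicate 1. With the authors' deposited values another locus was called, higher. For metformin against high fat diet it was 1 with the slide as a block, 1 without both arrays that stood apart and 0 to 1 when leaving out an array (1 without metformin replicate 3). For metformin against control it was 1 with the authors' deposited values, 4 at the unadjusted threshold and 0 to 1 when leaving out an array (1 without metformin replicate 2). The mean log2 difference of the chromosome 19 locus lay between -0.86 and -1.09 in all settings except the authors' deposited values (-0.58) and the log2 ratio to the partner (-0.14), and its adjusted p between 0.00224 and 0.981.

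The covariance of the diet and metformin differences, -0.0255, was -0.0154 with normexp and quantile normalization, -0.0160 with normexp and 75th percentile scaling, -1.08 with the authors' deposited values, -0.0360 without the filter, -0.0142 with the array column, -0.0353 for the log2 ratio to the partner, and -0.0465 to -0.0224 when leaving out an array. The difference in detection was 1.82 percentage points for metformin against high fat diet (-0.85 to 6.55; negative without high fat diet replicate 2, metformin replicate 1 or metformin replicate 2). It was -2.66 for metformin against control (-5.15 to 2.07; positive without metformin replicate 3) and -4.48 for high fat diet against control (-7.16 without its replicate 1 to -1.81 without its replicate 2).

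Of 934 values of 37 named differences under the alternatives, 891 kept their direction and their side of the threshold, 34 passed it, and 9 turned. With the log2 ratio to the partner, differences turned to -0.0361 (chromosome 3), 0.11 (mmu_circ_0001100), 0.00141 (chromosome 19), 0.0107 (chromosome 15) and 0.13 on the high fat diet, and to -0.35 and -0.0174 with metformin. With the authors' deposited values mmu_circ_0012020 turned to -1.60 and the chromosome 17 circRNA to -0.10 for metformin against high fat diet; where all arrays of both groups stood at the floor no value was given.

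Replicate numbers were not found to pair the arrays: deviations of same-numbered arrays correlated at -0.141 to 0.191 (mean 0.0171), 2 of 9 pairs above 0.1, and 4 of 9 arrays correlated best with their own number. With the replicate number as a block, 4 circRNAs (all lower) and 2 loci were called for high fat diet against control, no others. Host gene lists, several probes of a circRNA and a probe per host gene were not run. Signal over background limits dim circRNAs.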

Other observations

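Tests of linear RNA and of slide and scan for the arrays that stood apart were chosen only after the result was seen, as was the test of loci.

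None of the 10 brightest circRNA probes, at 255.5 to 375 times the array's 75th percentile on average, was called. In 9 of them the log2 differences were -0.32 to 0.04 between high fat diet and control and -0.34 to 0.17 between metformin and control. The other, mmu_circ_0015495, had -0.79 (limma, adjusted p = 0.408) and -1.17 (adjusted p = 0.351), and its _neg partner -0.91 and -1.09. A probe's brightness is not read as abundance of the circle. It carries the number next to that of mmu_circ_0015494, whose difference was -1.22. Whether these circles share a host gene was not determined. Of the loci with the most circRNAs, one on chromosome 11 (23270239 to 23321366) with 19 had a mean log2 difference of 0.03 between high fat diet and control and of -0.11 between metformin and high fat diet. One on chromosome 4 (126545961 to 126603267), also with 19, had -0.00477 and 0.05.

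Other loci with low p that missed the threshold differed in how their _neg partners went along. On chromosome 6 (116223591 to 116238186) 4 circRNAs were at a mean log2 difference of -0.72 ± 0.138 (SE, n = 3 arrays per group) on the high fat diet (limma, adjusted p = 0.118) while their partners stood at -0.13. On chromosome 17 (57541328 to 57559947) 5 circRNAs were at 0.70 ± 0.165 (adjusted p = 0.235) and their partners at 0.71. With metformin against control, 5 circRNAs on chromosome 19 (40228009 to 40242113) were at -1.11 ± 0.312 (adjusted p = 0.861) and their partners at -1.04. Of position-named circRNA probes on chromosome X, 72.3% were kept for testing, the lowest share of any chromosome, with a median level of -2.43.

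The differences of circRNA probes and their _neg partners correlated at 0.585 for high fat diet against control. A trend with signal level is argued against: with partners exchanged among pairs of like levels the correlation fell to a mean of 0.0243 over 100 exchanges. Position on the array does not account for it either, since the correlation with the nearest unrelated _neg probe was 0.0471, and the probes of a pair lay a median of 134 spots apart. A candidate explanation is that both probes report RNA of the same locus: a circRNA probe correlated at 0.469 with the _neg probes of other circRNAs of its locus, and at 0.404 with those of circRNAs that share neither end with it. Whether that RNA is circular, linear RNA left after digestion, or other transcripts of the locus stays open, as does a biological difference between the groups, since deviations within groups correlated too (0.402 to 0.592).

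High fat diet replicate 2 and metformin replicate 3 stood apart, with mean squared deviations from the other arrays 2.71 and 2.41 times the median of the other 7. Linear RNA left after RNase R was read by the 4 Gapdh and Pgk1 probes. Their median lay -0.05 and 0.0126 (log2) from the other 7 arrays. Relative to the array's other probes, these transcripts therefore moved little by their median. Levels were scaled within each array, so a rise of linear RNA shared by most probes would not show. Linear RNA of other genes was not read by these probes. Whether linear RNA set these arrays apart stays open. In the 25% brightest probes the ratio was 2.54 for high fat diet replicate 2, so that its deviation was not confined to dim probes. For metformin replicate 3 it was 1.68, and dim probes near background stay open. A difference between slides or scans does not set high fat diet replicate 2 apart from the 7 other arrays that shared both with it. The ratio of 2.71 is the value by which this array was singled out and adds no test. Effects within the slide, such as its place at column 2 and row 1, were not tested. For metformin replicate 3 (ratio 2.41), the single array of the second slide and scan, slide and sample cannot be told apart, and differences between pools of mice were not tested.

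For the lower signal of the chromosome 19 locus on the high fat diet, each of the 6 arrays was left out in turn. At least 0.911 of the log2 difference was kept, although the adjusted p was above 0.05 in 4 of these cases. The locus was singled out by the smallest p on these same arrays, which favours groups that differ on every array. The share kept therefore describes the locus and cannot decide whether a single array or chance lies behind the difference. Unspecific signal at the locus remains a candidate explanation, since the _neg partners carried 0.860 of the difference. A change of the locus' RNA with diet, circular or linear, stays open as well and was not told apart from it.

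The 10 splits of 6 arrays are too few for a share under 0.05. For single circRNAs the real split gave 0 calls in each comparison, so that all 10 splits gave as many; the highest other count was 0 for high fat diet against control, 3 for metformin against high fat diet and 0 for metformin against control. For loci the real split of high fat diet against control gave 1 call, which 1 of the 10 splits (the real one) reached, and the highest other was 0; at an unadjusted p under 0.05 it gave 102 loci, where 5% would be 53.3 and the highest other split gave 81. For both other comparisons the real and the highest other count of loci were 0, so that all 10 splits gave as many. The split with 3 calls set high fat diet replicate 1 and metformin replicates 1 and 2 against the rest, with 3063 circRNAs at an unadjusted p under 0.05 against 1007 for the real one (for high fat diet against control the highest other was 2024 against 1868, and for metformin against control 1501 against 1307). The 3 arrays on the other side had the lowest detection (71.7%, 77.0% and 69.4%). This split was the highest of 10 and its detection was looked at afterwards. Whether a structure of the samples other than treatment lies behind it was not tested. Leaving out high fat diet replicate 2 and metformin replicate 3 gave 0 called circRNAs for metformin against high fat diet. Over the 3 groups together, 1378 of 24546 circRNAs had an unadjusted p under 0.05 in limma's F test, and 20 of 100 drawn splits of the 9 arrays gave as many (highest other 2710), so that chance could not be excluded.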
